A study of Mus musculus with 2 samples.

How the data were processed

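The data were Ring1b ChIP-seq intervals from sorted, EdU-labelled incisor pulp cells of CD1 mice. The labels give 1 Ring1b ChIP sample and 1 input sample, whereas the file headers name replicates 1 and 2 of the ChIP and a pooled input. Since the labels give 1 ChIP sample, the 2 sets were called runs and counted as 1 sample, and it stayed open whether they are biological replicates. Per the submitters' processing notes, BWA and SICER were used with mm10, and no versions or settings are given there. Per the file headers, the authors deposited a summit track, an interval track for each run and a track of merged regions. Interval widths were multiples of 200 bp, a window size usual for SICER, in 0.430% of cases.

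The deposited gene table gives the peak height (a signal value) of each gene's highest interval, the mean height in each run, and the number of intervals assigned. The deposited interval file gives a score for each summit, which is the same height. The authors' scaling of these signal heights is not given in the sources used here. A deposited list of track addresses was not used. The largest gap between an interval and an assigned gene was 9992 bp.

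Everything else was computed from those tables with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9. Gene starts and strands came from the deposited table. Protein-coding genes came from a reference gene table of GRCm38.p6, the build mm10 names, which gives no strand. Of 3993 deposited gene identifiers, 3867 were found in it and 3461 were among its 21887 protein-coding background genes. Of 2681 of those genes overlapped by a region, 96.1% were in the deposited table. Because strand is lacking for unbound genes, random placements were scored against either gene end. No genome sequence was used, so GC and CpG content were not measured.

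The gene lists, the list tests, the rule for named genes and most alternatives were fixed before the data were examined. Most tests of explanations in the closing section were chosen after the result was seen. A share carries an exact Clopper-Pearson 95% interval, which covers counting error only. Each list's share was ranked among 10000 random lists matched on gene length decile. Median heights were ranked among 10000 random sets of bound genes, for lists with at least 3 bound members. A list was called high above the 99th percentile and low below the 1st. These percentiles describe this sample and are not p-values. Named genes were those of the 10 highest and 10 widest regions, up to 4 bound members per list by height, the first 3 unbound members in list order, the Zic genes, the CDK inhibitors, Rnf2, Ring1 and Bmi1. Some genes that this rule takes are not reported here. The genes of the closing family survey were named after their values were seen.

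The list test was tested on simulated data, in which regions were placed at random and 200 genes of the 21887 were given an interval. All 30 lists made only of such genes, with a share fixed at 100%, were called high. Where 40% of a list's genes were given an interval, 14 of 20 lists of 7 genes and 20 of 20 lists of 15 or of 30 genes were called high. The 24 fixed lists were also tested in 10 simulations with nothing planted. Of these 240 calls, 5 were high and 0 low. Regions were placed at random there, whereas 60.2% of the real regions lay near a gene end, so this rate may not hold for the real regions.

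Alternatives used other windows, stricter heights, autosomes only, unmatched lists and neighbouring genes as 1 unit. Heights are whole numbers with many ties. The stricter sets were planned as the top 50% and top 25% of regions by height. In a first computation their percentile cutoffs, 4 and 5, kept 75.8% and 45.7% of regions. The cutoffs were then set to the whole numbers whose kept shares are closest to those planned, which are 5 or more (45.7%) and 6 or more (24.6%). This was done after results had been seen. It changed the calls of housekeeping genes, Polycomb subunits, Wnt receptors and effectors, and BMP and TGF-beta genes, whose values are given below. The classes of high and low run 2 height used in the closing section were reset in the same way. Cutoffs at the median, each run alone and the family survey, with and without members of the fixed lists, were added after seeing the data.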

Results

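Ring1b, the catalytic ubiquitin ligase subunit of Polycomb repressive complex 1 (PRC1), was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in cells from the incisor pulp of CD1 mice at postnatal day 5. The cells had been sorted for 5-ethynyl-2'-deoxyuridine (EdU), a thymidine analogue taken up during DNA synthesis. EdU was given as 1 dose of 3.3 µg per g, 24 h before collection. The labels describe 1 Ring1b ChIP sample and 1 input DNA sample. The tables used here hold 2 sets of ChIP intervals, named replicate 1 and replicate 2 in the file headers, and no input values, so ChIP was not compared with input. Whether these came from separate animals or cell pools is not given in the sources used here. They are called run 1 and run 2 below and were counted as 1 sample, so no SD is given and no p-value was computed. If they were separate replicates, the differences between the runs given below are the spread between replicates. Sequencing depth was not given in the sources used here. Summit heights are the authors' own values, whole numbers whose scaling is not stated. They were used to describe, rank and filter intervals, and in the closing section to compare the runs. Coordinates are in mm10.

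The first question was how much of the genome carried Ring1b and at which loci it was highest. The authors' merged set held 4316 regions that covered 3.51 Mb. Their median width was 671 bp, with a range of 248 to 8441 bp. Most regions were low: the median summit height was 4, and 164 regions (3.80%) reached 10 or more. Genes of the fixed Hox and developmental transcription factor lists held 4 of the 10 highest regions, at Otx1, Evx2 with Hoxd genes, Meis2 and Tbx15. Otx1, a homeobox gene of forebrain development, had a region of height 27 on chromosome 11 at 21991976 to 21995385. Tal1, a regulator of blood formation, had one of height 24 on chromosome 4 at 115056135 to 115059474. A region of height 23 on chromosome 2 at 74667066 to 74670456 was assigned to Evx2 and to Hoxd13, Hoxd12 and Hoxd11 of the Hoxd cluster. Meis2, which encodes a Hox cofactor, reached 22, and Tbx15, a T-box gene, reached 21.

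Not all of the highest regions lay at developmental genes. The top region, of height 66, lay on chromosome 17 at 39842844 to 39848998 over Rn18s-rs5, an 18S ribosomal RNA gene, inside the longer model Gm21946. A region of height 41 on chromosome 5 at 146260578 to 146261513 lay inside Cdk8 and over the microRNA gene Mir5105. A region of height 26 on chromosome 16 at 11143872 to 11144400 was assigned to Zc3h7a and Txndc11. Another, of height 25 on chromosome 3 at 5860336 to 5860940, was assigned to no gene. None of these 4 regions was called in run 1, and neither were those at Otx1, Hoxd13, Meis2 and Tbx15.

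The widest region, 8441 bp on chromosome 11 at 96004081 to 96012521, lay at Igf2bp1, which encodes an RNA-binding protein of fetal tissues. The next, of 7881 bp, lay at its paralogue Igf2bp3 on chromosome 6. Wide regions also lay at Fezf1 and Cadps2 (7396 bp), Lbx1 (6692 bp), Otx1 and Ehbp1 (6226 bp), Gata6 (6110 bp), the Hoxa9 to Hoxa11 part of the Hoxa cluster (5181 bp) and Sim2 (5167 bp).

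The runs differed in yield. Run 1 gave 465 intervals with heights up to 9, and run 2 gave 3938 with heights up to 66. Of the run 1 intervals, 77 (16.6%, exact 95% interval 13.3 to 20.3%) overlapped a run 2 interval by at least 1 bp. In 1000 random placements the median was 1 and the maximum 5. Of the merged regions, 73 were called in both runs, 388 in run 1 only and 3855 in run 2 only. Run 1 called 1.34% of the run 2 intervals of height 2 to 3 (12 of 896) and 25% of those of height 15 or more (9 of 36).

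**Figure D1:**
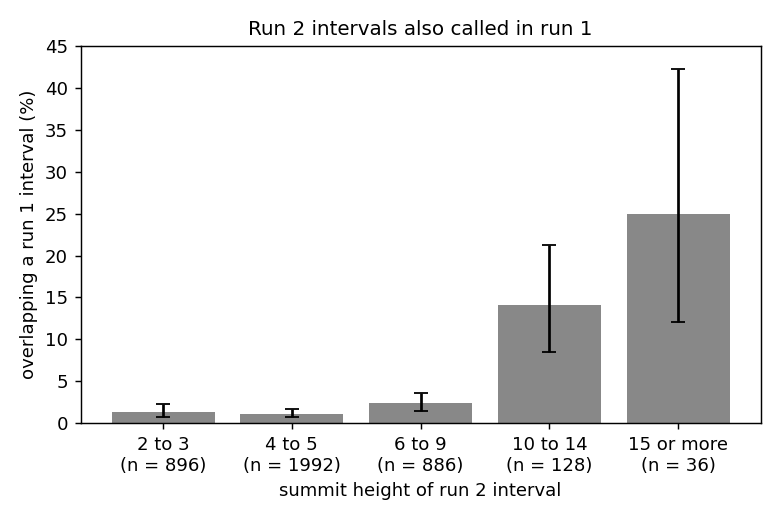
Share of run 2 intervals that overlapped a run 1 interval (y axis, %), by run 2 summit height (x axis, n = intervals per class); error bars are exact 95% binomial intervals, which cover counting error only. The share was 1.34% at heights of 2 to 3 and 25% at 15 or more.

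Ring1b lay mostly at gene starts. Of the 4316 merged regions, 2577 (59.7%, exact 95% interval 58.2 to 61.2%) overlapped a transcription start of an assigned gene within 2.5 kb, and 749 (17.4%) overlapped a gene's 3' end in the same window. The runs differed here: 64.0% of run 2 intervals lay at a start, against 23.9% of run 1 intervals. Regions of height 2 to 3 lay at a start in 50.5% of cases those of height 6 to 9 in 71.3%, those of 10 to 14 in 70.3% and those of 15 or more in 66.7%. Within 2.5 kb of either end of a protein-coding gene lay 60.2% of regions, against 6.74 to 9.52% in 1000 random placements on the same chromosomes. The placements could also fall on sequence to which reads cannot be mapped.

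The authors' table assigned at least 1 interval to 3993 genes, counting intervals up to 10 kb from a gene. Of the 4316 regions, 552 (12.8%) were assigned to no gene. Run 2 intervals were assigned to 3751 genes, run 1 intervals to 434, and intervals of both runs to 192. Among 21887 protein-coding genes, 3461 (15.8%) had an interval, and this share is the background for the gene lists. The background includes gene families that were almost never bound. Of 1109 olfactory receptor genes 2 had an interval, and of 355 vomeronasal receptor genes 1 had one.

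Hox genes, which set position along the body axis, were almost all bound. An interval was assigned to 38 of 39 (97.4%, exact 95% interval 86.5 to 99.9%), and Hoxb1 was the exception. With run 1 alone, 10 of 39 (25.6%) had one, still above the 99th percentile. The share lay above the 99th percentile of 10000 random lists matched on gene length, whose median was 12.8%. The median height of the bound members was 9, against 4 over all bound protein-coding genes, again above the 99th percentile. With the interval nearest to each start in place of the highest, the median was 5, at percentile 89.1, which ended the height call. With intervals within 2.5 kb of the start, the median was 7 and the call held. Within 2.5 kb of the start, 31 of 39 (79.5%) had an interval. Hoxd11, Hoxd12 and Hoxd13 reached 23 and Hoxa10 reached 16. Regions covered 51.6% of the Hoxa cluster and 41.2% of Hoxd, and 13.5% of Hoxb and 15.8% of Hoxc, against 0.130% of the annotated span of all chromosomes. Neighbouring Hox genes share intervals. Counted as 4 clusters, all 4 were bound, at percentile 92.1 of random runs of as many neighbouring genes. This is the highest count possible, so no high call could be reached by cluster.

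**Figure D2:**
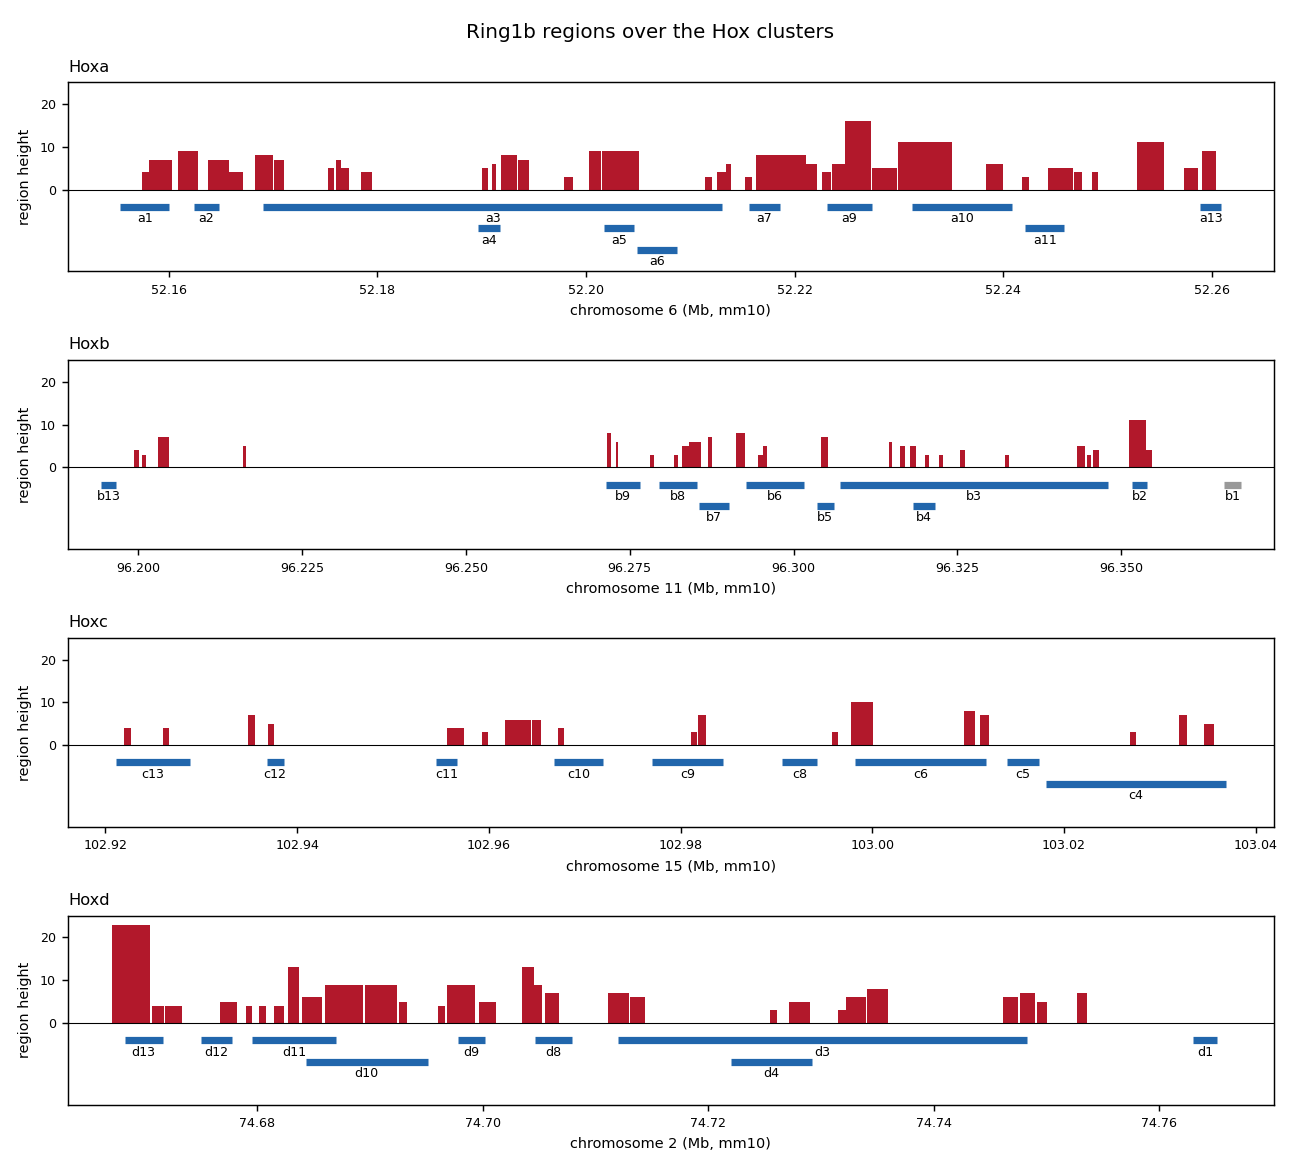
Merged Ring1b regions (red bars, y axis: summit height; bar width to scale) over the 4 Hox clusters in mm10 (x axis, Mb). Lines below 0 are genes, blue with an assigned interval and grey without. Regions covered 51.6% of Hoxa and 13.5% of Hoxb.

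All 5 Zic genes, zinc finger factors of neural and skeletal patterning, had an interval (exact 95% interval 47.8 to 100%), above the 99th percentile. Within 2.5 kb of the start, 3 of 5 (60%) had one. With run 1 alone, 1 of 5 had one (percentile 97.1), below the call. Zic2 reached 17, Zic5 reached 14, Zic4 reached 8 and Zic1 reached 7. Zic2 and Zic5 are neighbours on chromosome 14, as are Zic1 and Zic4 on chromosome 9. Of the other developmental transcription factors, 70 of 78 (89.7%) had an interval, with a median height of 9. Share and height both lay above the 99th percentile. Otx1 (27), Evx2 (23), Meis2 (22) and Tbx15 (21) were highest, and Pax1, Sox3 and Sox14 were among the 8 without one. Of these 70 genes, 68 had an interval within 2.5 kb of the start.

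Transcription factors of tooth and jaw mesenchyme were also bound more often than random lists, at 23 of 30 (76.7%, exact 95% interval 57.7 to 90.1%). Their median height of 5 lay at percentile 74.6, below the call, whereas their median interval width of 1011 bp, against 677 bp over all bound genes, lay above the 99th percentile. Pitx1, a hindlimb and jaw homeobox gene, reached 12. Tfap2b, a neural crest factor, reached 11, and Gsc reached 10. Dlx3, Dlx4 and Alx1 had no interval.

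Neither genes of the differentiated tooth nor incisor stem cell and pericyte markers were called high. Of 15 odontoblast and mineralised matrix genes, 1 had an interval (6.67%, percentile 20.7), Wnt10a at 5. With starts within 10 kb, 0 of 15 lay at percentile 7.44, so a list of this size could not be called low there. Dspp and Dmp1, which encode dentine matrix proteins, and Ibsp had none. Incisor mesenchymal stem cell and pericyte markers had intervals at 5 of 16 genes (31.2%, percentile 92.1), among them Axin2 (8), Foxd1 (6), Gli1 (4) and Pdgfra (4). Thy1, Cspg4 and Pdgfrb had none.

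Among Wnt receptors and effectors, intervals were assigned to 12 of 27 (44.4%, exact 95% interval 25.5 to 64.7%, percentile 99.9), with Ctnnb1, which encodes beta-catenin, Dvl1 and Fzd1 at 6 and Fzd8 at 5. Fzd2, Fzd3 and Fzd4 had none. The call ended when only regions of height 6 or more, 24.6% of all regions, were kept (11.1%, percentile 89.0), at or above the median height (33.3%, percentile 98.9) and with run 1 alone (3.70%, percentile 69.9). Wnt ligands had intervals at 4 of 19 genes (percentile 72.8), Wnt5b at 8, Wnt5a at 7, Wnt10a at 5 and Wnt3a at 3, and not at Wnt1, Wnt2 or Wnt2b. Wnt inhibitors had intervals at 7 of 27 (percentile 85.7). Shisa3 reached 11, Axin2 reached 8, and Dkk1 and Kremen1 reached 5, whereas Dkk2, Dkk3 and Dkk4 had none. The difference between the Wnt lists was not tested.

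Inhibitors of cyclin-dependent kinases, which hold cells out of the division cycle, were bound at 5 of 7 genes (71.4%, exact 95% interval 29.0 to 96.3%, above the 99th percentile). Cdkn1b reached 8, Cdkn2a reached 7, Cdkn2b and Cdkn2c reached 6 and Cdkn1c reached 3. Cdkn1a and Cdkn2d had none. Cdkn2a held 9 intervals; it adjoins Cdkn2b on chromosome 4. All these intervals came from run 2. Cyclins, kinases and other cell cycle genes were bound at 7 of 44 (15.9%, percentile 51.3), with Cdk4 at 5 and Ccnd1, Ccne2 and Cdk6 at 4. Ccna1, Ccna2 and Ccnb1 had none.

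Genes for Polycomb subunits were themselves bound at 15 of 30 (50%, exact 95% interval 31.3 to 68.7%, above the 99th percentile). Pcgf1 reached 11, Bmi1 reached 8, and Cbx2 reached 5. Ring1, the paralogue of Ring1b, reached 4, from an interval upstream of its start. Rnf2, which encodes Ring1b, had none, nor had Pcgf3 or Pcgf5. The median height of 4 lay at percentile 25.9. Housekeeping genes, described below, were bound at 13 of 27 with a median height of 5. The share of Polycomb subunits therefore does not set them apart from housekeeping genes. The call held at or above the median height (43.3%) and at heights of 5 or more (23.3%, percentile 99.1). At heights of 6 or more, 6.67% of the list had an interval (percentile 70.1), which ended the call, as did run 1 alone (3.33%, percentile 70.3).

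BMP and TGF-beta signalling genes were bound at 14 of 35 (40%, exact 95% interval 23.9 to 57.9%, percentile 99.9), with Smad3, Smad7 and Tgfb2 at 7 and Id3 at 6. Bmp2, Bmp3 and Bmp4 had none. At heights of 5 or more, 45.7% of all regions, the share was 20% (percentile 97.2), below the call, and at 6 or more it was 17.1% (percentile 99.7), above it. With run 1 alone it was 2.86% (percentile 66.8), below the call. FGF genes were bound at 3 of 25 (percentile 29.0), Fgfr3 at 6, Fgf9 at 4 and Fgf3 at 3, and Fgf1, Fgf2 and Fgf4 had none. Hedgehog genes were bound at 5 of 14 (percentile 92.0), Ptch1 at 8, Smo at 6, and Gas1 and Gli1 at 4. Shh and Dhh had none.

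Marker lists of other cell types lay between the 1st and 99th percentiles. With starts within 2.5 kb, 0 of 16 immune markers lay at percentile 8.26, so a list of this size could not be called low there. Dental epithelium and ameloblast markers had 1 of 15, Trp63 at 3. Endothelial markers had 2 of 13, Flt1 at 5 and Erg at 4. Immune markers had 1 of 16, Cd68 at 6. Glial, Schwann and neuronal markers had 3 of 14, with Rbfox3 at 4 and Erbb3 and Tubb3 at 3. Erythroid markers had 2 of 10, among them Tal1 at 24, and muscle and heart markers had 1 of 14, Pax7 at 7. Amelx, Pecam1, Ptprc, Sox10, Hba-a1 and Myod1, 1 from each of these lists, had no interval.

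Housekeeping genes were bound at 13 of 27 (48.1%, exact 95% interval 28.7 to 68.0%, above the 99th percentile), with Polr2a, Ppia and Ywhaz at 6. Heights of the bound members were 3 to 6, with a median of 5 (percentile 73.4), against 4 over all bound protein-coding genes. The share lay near those of Polycomb subunits (50%), Wnt receptors and effectors (44.4%) and BMP and TGF-beta genes (40%). At heights of 6 or more the housekeeping share was 11.1% (percentile 93.7) and with run 1 alone 3.70% (percentile 82.9), both below the call. Ribosomal protein genes were bound at 8 of 42 (19.0%, percentile 81.1), with Rpl10a, Rpl24 and Rps6 at 5. Olfactory receptor genes, which form large silent clusters, had an interval at 2 of 1109 (0.180%, exact 95% interval 0.020 to 0.650%), below the 1st percentile.

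**Figure D3:**
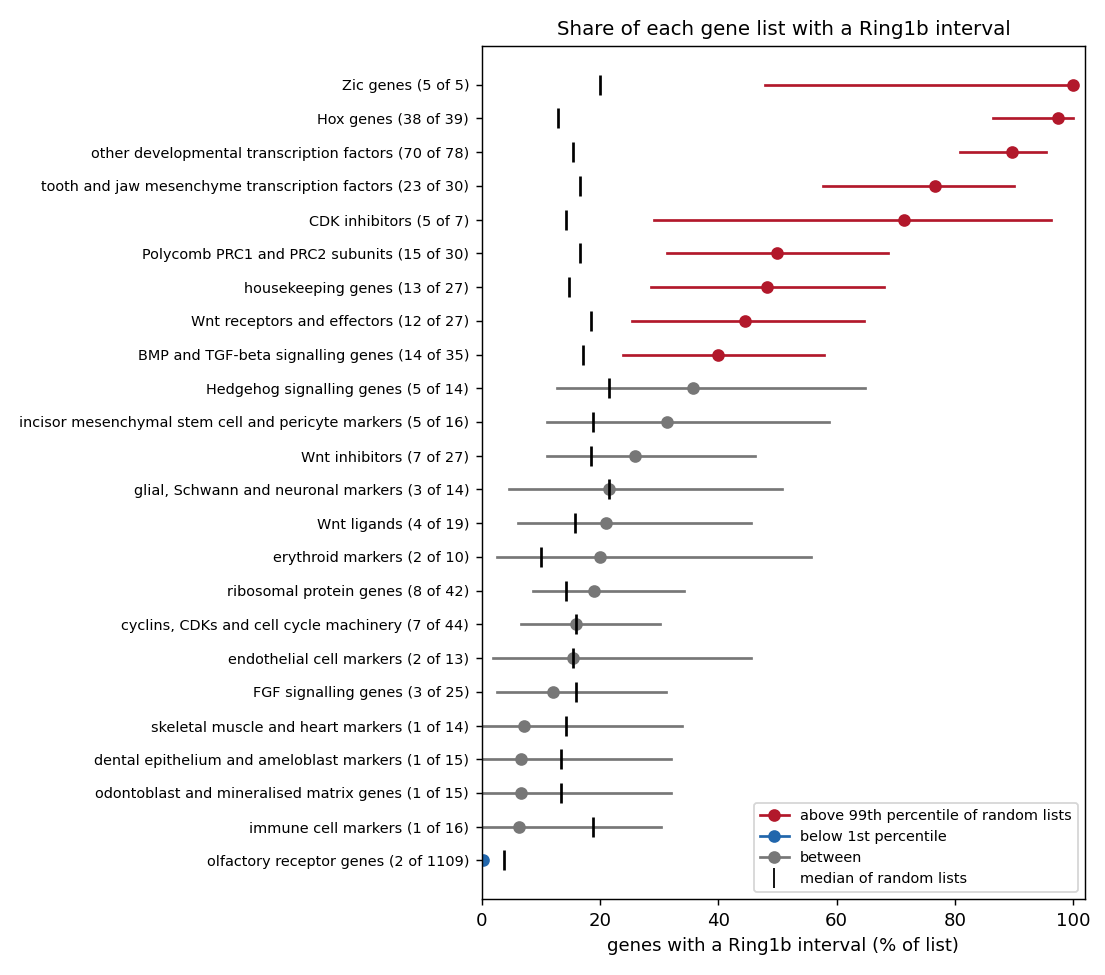
Share of each gene list with a Ring1b interval (x axis, %; points), with exact 95% binomial intervals (lines, counting error only) and the median of 10000 length-matched random lists (black ticks). Red lists lay above the 99th percentile, blue below the 1st; Hox genes stood at 97.4% and olfactory receptor genes at 0.180%.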

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

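The alternatives with each run alone and with heights at or above the median were chosen after seeing the data. No paired analysis was possible because the labels give 1 sample per group. The GC and CpG alternatives were not run, for lack of a genome sequence. Autosomes only, unmatched random lists and starts within 1, 2.5 or 10 kb changed no list's call.

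Counts followed the threshold. The 4316 regions became 1062 at heights of 6 or more and 465 with run 1 alone. The 3993 genes became 2585 and 2376 with starts within 2.5 and 1 kb, 2017 and 1114 at heights of 5 or more and 6 or more, and 434 with run 1 alone. The share of regions at a start was 52.0, 67.3 and 73.9% with windows of 1, 5 and 10 kb and 57.8% by midpoint. It was 62.7% at or above the median height, 66.9% at 5 or more, 71.0% at 6 or more, 23.9% in run 1 and 64.0% in run 2.

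At heights of 6 or more, Wnt receptors and effectors (11.1%), Polycomb subunits (6.67%) and housekeeping genes (11.1%) were no longer called high. BMP and TGF-beta genes lost the call at 5 or more (20%) but not at the median or at 6 or more (17.1%, percentile 99.7), and Wnt receptors lost it at or above the median height (33.3%, percentile 98.9) but not at 5 or more (29.6%, percentile 99.8). These 2 calls thus lie near the 99th percentile. With the interval nearest to the start, the median height of Hox genes was 5 (percentile 89.1) and that of Zic genes 5 (percentile 75.8), both without a call, while other developmental factors kept theirs. By interval width in place of height, tooth and jaw factors became high (1011 bp) and ribosomal protein genes low (498 bp, percentile 0.480). The Hox share by cluster was 100%, the highest possible, and lay at percentile 92.1, so no high call could be reached. With run 1 alone, shares were 25.6% for Hox genes, 17.9% for other developmental factors and 13.3% for tooth and jaw factors, all still called high. In run 1, calls ended for Zic genes (20%), Wnt receptors (3.70%), CDK inhibitors (0%), Polycomb subunits (3.33%), BMP and TGF-beta genes (2.86%), housekeeping genes (3.70%) and olfactory receptors (0%), and erythroid markers gained one (20%). Run 1 held fewer intervals, which lowers shares, and fewer of its intervals lay at a start (23.9%, against 64.0% in run 2). Their parts in the lower shares were not separated. For olfactory receptors, 0 of 1109 is the lowest count possible and still lay at percentile 1.38, so no low call could be reached. The cause of each other lost call was not tested. Of the 95 named genes with an interval, 64 kept one at 6 or more and 23 in run 1.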

Other observations

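Gene families were picked by symbol after the values were seen, and members of the fixed lists were then left out. Of the remaining genes, intervals were assigned to 17 of 35 Fox genes (48.6%), 5 of 10 T-box genes, 3 of 3 LIM homeobox genes, 6 of 10 Nkx genes, 6 of 11 Sox genes, 11 of 23 Sp and Klf genes and 8 of 14 Prdm genes, all above the 99th percentile of length-matched lists. Other transcription factor families were not called among the remaining genes. These were POU (4 of 12, percentile 93.3), Hes and Hey (4 of 9, percentile 98.2), Gata (1 of 2) and Irx (0 of 2). With members of the fixed lists kept, 7 of 15 POU, 4 of 6 Gata and 4 of 6 Irx genes were bound, each above the 99th percentile. Zfp genes, the largest family surveyed, had 43 of 367 (11.7%, percentile 1.22). Splicing factor genes, at 16 of 52 (30.8%), lay above the 99th percentile, whereas proteasome subunit genes, at 7 of 37 (percentile 74.0), did not. Protocadherin genes (1 of 69), solute carrier genes (42 of 345), keratin genes (0.980%), vomeronasal receptor genes (1 of 355) and defensin genes (0 of 71) lay below the 1st percentile. In this survey each gene counted singly. Neighbouring genes were not taken as 1 unit, as they were for the fixed lists, so the calls of clustered families carry that limit.

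Of the tests below, those on run 1 height by run 2 height, on housekeeping and ribosomal protein genes and on ribosomal RNA were chosen or reset after the result was seen. No biological explanation was tested, since the design gives 1 ChIP group.

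The runs shared few intervals. Run 2 heights are tabulated per gene, so they were read at 187 of the 388 regions called in run 1 alone, those whose gene held no other region. Their median run 2 height was 0, which argues against sites that just missed the run 2 threshold. Of all 388 run 1 intervals that overlapped none of run 2, 17.8% lay near a gene end, against at most 12.1% in 1000 placements, so background placed at random does not account for all of them. Run 1 heights could likewise be read at only 1968 of the 3855 regions called in run 2 alone, of which 4 had a run 2 height of 15 or more. At these 1968 regions, mean run 1 height was 0.845 where run 2 height was 6 or more (n = 419). It was 0.472 where run 2 height was 3 or less (n = 475), a difference of 0.373 (bootstrap 95% interval 0.239 to 0.525). Here too the median was 0: 1176 of the 1968 regions had a run 1 height of 0. Some run 2 sites may thus be present in run 1 below its threshold, but most of these regions had no run 1 height. A difference in depth or enrichment between the runs stays open.

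Housekeeping genes were often bound, with a median height of 5, against 4 over all bound protein-coding genes (percentile 73.4). At heights of 6 or more, 11.1% had an interval, at percentile 93.66, and at 5 or more the share was 29.6%, above the 99th percentile. No housekeeping interval was higher than 6, so the stricter cutoff removes most of them by construction and decides nothing about low background at open promoters. Expression alone was not excluded either: ribosomal protein genes lay at percentile 81.08 and their interval (8.60 to 34.1%) overlapped that of housekeeping genes (28.7 to 68.0%). Of the families picked after the values were seen, splicing factor genes lay above the 99th percentile and proteasome subunit genes at percentile 74.0. Background at open promoters and weak true binding cannot be told apart here, for lack of input values. The same limit holds for Polycomb subunits (15 of 30 bound), Wnt receptors and effectors (12 of 27) and BMP and TGF-beta genes (14 of 35). Their shares lay near that of housekeeping genes (13 of 27), and their median heights were 4, 5 and 4.5. Of these lists, only BMP and TGF-beta genes were still called high at heights of 6 or more (17.1%).

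The highest interval lay at a ribosomal RNA gene. Run 1 called nothing there, although its height at Rn18s-rs5 was 19 and its highest called interval had a height of 9. Why the locus was not called was not tested. The height of 19 lay at percentile 99.97 of run 1 heights at regions called in run 2 alone. The run 1 height at Mir5105 was 3, at percentile 98.4. Run 1 height rose with run 2 height, and both loci were chosen as the highest in run 2. Reads of a multicopy gene gathered on 1 copy and true binding therefore cannot be told apart by these values, and input values were not analysed here.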
